A study of Mus musculus with 30 samples.

How the data were processed

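RNA from 30 subcutaneous B16F10 melanomas was sequenced. The tumors grew in wild type (WT) and ARE-del heterozygous (HET) female C57BL/6 mice, per the labels. The tumors titled WT carry the genotype label "ARE-del +/+", read here as wild type. Per the labels' protocols, cultured low-passage tumor cells were injected under the skin of the flank. After 7 days of growth the mice received antibodies 2 times a week: control rat IgG2A, 0.25 mg of anti-PD1, 0.25 mg of an agonist anti-CD40, or both (called the combination here). The tumors were frozen on dry ice, RNA was extracted with the Maxwell 16 LEV simplyRNA tissue kit and libraries were made with an Illumina TruSeq kit, per the labels' protocols. Nothing in the labels says that replicates are separate animals, so the p-values measure the spread between these samples.

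The deposited table holds 1 column for each of the 30 libraries and 18975 genes, each with a versioned Ensembl identifier and a symbol. Reads were aligned with STAR to mm10 and normalized with edgeR, per the submitters' processing notes, which give no versions. The deposited values are log2 CPM (read counts scaled to library size) made by the authors. From the values themselves, the scale is an effective library size for each library, with a prior count of 2 reads scaled to library size. Each value could be taken back to a whole read count within a tolerance of 0.01 reads, for 100% of the values in every library. The recovered reads ranged from 17.6 M to 36.0 M per library, with a median of 24.9 M. One read equals 0.0596 CPM in the shallowest library and 0.0276 CPM in the deepest, and a gene with no read has a log2 value of -3.64. Where a gene had no read in a group, 3 reads over the group served as the floor, which covers counting error only. Strandedness, the filter on low genes and the annotation release are not stated. Without strand, reads of overlapping genes cannot be told apart. How reads shared by near-identical genes were assigned is not stated either, so folds of class I and class II MHC genes, hemoglobin genes and interferon-induced gene families are uncertain in how they divide between family members. Of the 18975 identifiers, 18837 were found in GENCODE vM21 (the mm10 assembly), 17791 of them with the same symbol, and 11 symbols belong to more than 1 gene of the table. Coordinates are 1-based, from that annotation.

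The main fit and the gene lists were fixed before the data were examined. Genes with a log2 value above 0 in at least 3 libraries were kept, 15002 in all. A linear model with 1 mean for each of the 8 groups was fitted to the deposited log2 values of all 30 libraries with limma 3.58.1 (moderated test, intensity trend) in R 4.3.3. From it came 17 comparisons: each treatment against IgG within a genotype, HET against WT under each treatment, the combination against each single antibody, and the difference between genotypes in the response to each treatment (the interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes kept. Standard errors of log2 differences of genes are limma's. Those of list score differences come from an ordinary linear model of the scores of all 30 libraries, without limma's moderation.

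The 26 gene lists cover interferon responses, antigen presentation, immune cell types, tumor cell programs, stroma, and the skin, muscle, fat and blood that a tumor sample can hold. Lists with at least 4 measured members were tested with limma's camera, which asks whether members stand higher or lower than the other genes, at a preset correlation between members of 0.01. Members are the genes that passed the filter: 6 of 22 cytotoxic and NK, 8 of 23 T cell and 4 of 15 B cell genes. A scarce gene passed where at least 3 libraries held it, so the members left can be those high in some group. The adjusted p is over the 26 lists of a comparison. Each test was repeated with the correlation estimated from the data. In a check on simulated data, 46 of 100 unchanged lists of 20 members that correlate at 0.5 were called with the preset correlation and 0 with the estimated one. A call with the preset correlation alone is therefore given as where a list stood in these libraries. After the values were seen, a two-sided exact permutation test was added. It uses the mean log2 value of a list per library (the list score) or the log2 value of a core gene. For an interaction it permutes genotype within the treated and within the IgG libraries, taking both arms to be free of a genotype difference. Its p was adjusted over the 26 lists, or over the core genes within a comparison.

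Genes named in the text follow a rule. Ifng, Pdcd1, Cd274 and Cd40 are given in every group. For each comparison, the 10 highest and 10 lowest called genes with every library of the first group on the same side of the other group's mean are named, and for each reported list up to 4 called members. Where a list has no called member, its 2 members with the highest mean value are given as values. For the IFN-γ response list 1 of these is given and the other is not used here. No gene was called in any comparison, so the genes named from lists come from the last part of the rule. Which lists are described in each comparison was chosen after the values were seen, and so were Cd8a, Itgal, Il18bp, Psmb8, Mndal, Casp1, Ubd, Ciita, H2-Aa, Xist and the abundant genes of 1 library.

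The alternatives chosen at the start were no filter or a stricter filter (mean log2 above 2), 1 added to the linear values, quantile normalization, no intensity trend, library weights, a fit of the compared groups alone, the replicate number as a block, leaving out each library in turn, and the L number. The L number is a number from 5 to 8 that starts each description. Its meaning is not stated, and it was used as a possible batch, as a covariate and by comparing libraries within 1 number. Library weights were estimated gene by gene, since the default estimate did not converge. Added after the data were seen were limma's voom on the recovered reads, and the keratinocyte and skeletal muscle list scores of each library as covariates. Simulated log2 values of 15002 genes were drawn with independent normal noise for each gene. They held no counting step and no variation shared between genes, so recovery in the real libraries can differ. For HET anti-CD40 against HET IgG the fit recovered 10.0% of genes changed by a log2 fold of 0.5, with 8 false calls. It recovered 54.0% at a fold of 1, 86.0% at 2 and 98.0% at 3. For the interaction with anti-CD40 it recovered 2.0%, 10.0%, 78.0% and 88.0%, with 5 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.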

Results

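Gene expression was measured by RNA sequencing in 30 subcutaneous B16F10 tumors, a transplanted mouse melanoma, from wild type (WT) mice and mice heterozygous for the ARE-del allele (HET). ARE-del lacks an AU-rich element in the 3′ untranslated region (UTR) of Ifng, the gene of interferon-gamma (IFN-γ), and such elements shorten the life of an mRNA. The tumor cells do not come from these mice, so the allele is carried by the host cells of a tumor. By its title, the series asks how defined IFN-γ levels bear on antitumor responses and on immunotherapy in hosts with underlying autoimmunity. WT mice gave 5 tumors after control IgG, 4 after anti-PD1 (against the T cell checkpoint receptor PD-1), 3 after agonist anti-CD40 (against a receptor that activates antigen-presenting cells) and 3 after the combination. HET mice gave 4, 3, 4 and 4 tumors in the same order. Reads per library ran from 17.6 M to 22.6 M for WT IgG, 21.2 M to 28.0 M for WT anti-PD1, 21.9 M to 25.1 M for WT anti-CD40 and 21.1 M to 27.6 M for the WT combination. For the HET groups they ran from 21849047 to 29995970 for IgG, 24.0 M to 26.8 M for anti-PD1, 25.9 M to 31.2 M for anti-CD40 and 27.4 M to 36.0 M for the combination.

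Ifng mRNA was scarce in every group, with at most 40 reads over the libraries of a group, and most of its reads came from HET tumors given anti-CD40 alone or in the combination. Ifng (ENSMUSG00000055170.3, mm10, chromosome 10, 118441046 to 118445892, plus strand) has 4 exons, and its 3′ UTR spans 118445262 to 118445892 in exon 4. HET anti-CD40 tumors held 40 Ifng reads in 3 of 4 libraries, 0.363 ± 0.524 CPM (SD, n = 4), but 31 of the reads were in replicate 3, without which the mean was 0.104 CPM. HET combination tumors held 20 reads in 4 of 4 libraries, 0.168 ± 0.141 CPM (SD, n = 4). WT anti-PD1 tumors held 9 reads in 2 of 4 libraries, 0.088 ± 0.106 CPM (SD, n = 4). The other groups held 0 reads (WT IgG and HET anti-PD1), 1 read (WT anti-CD40 and HET IgG) or 2 reads (WT combination). The mean of WT anti-PD1 was 3.0-fold the floor of 3 reads over WT IgG, and that of the HET combination 4.3-fold the floor of HET anti-PD1. The counting error of the few reads in the higher group is not in these ratios, so they are not lower bounds of a fold. They were 1.5-fold without WT anti-PD1 replicate 1 and 2.7-fold without HET combination replicate 3. The log2 difference was 1.62 for HET anti-CD40 against HET IgG (exact p = 0.14, n = 4 and 4) and 0.89 without replicate 3, and it was 1.31 for the HET combination (exact p = 0.057, n = 4 and 4). HET against WT gave 1.53 under anti-CD40 (exact p = 0.2, n = 4 and 3), 0.81 without the same replicate, and 1.15 under the combination (exact p = 0.11, n = 4 and 3). None of these differences passed the test, and at this depth a difference of a few reads was not detectable. Reads counted over the whole gene do not check the genotype labels, since the allele lacks part of the UTR alone.

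Cd8a, a marker of cytotoxic T cells, Cd40, the receptor that the agonist antibody binds, and Pdcd1, which encodes PD-1, had their highest group means in HET tumors given anti-CD40 alone or in the combination. For Cd8a in both groups, and for Pdcd1 in HET anti-CD40, these ranks rested on replicate 3. No difference of these genes, or of Cd274, which encodes the PD-1 ligand PD-L1, passed adjustment. Cd8a (ENSMUSG00000053977.9, chromosome 6, 71373427 to 71379173) stood at 0.074 ± 0.127 CPM in HET IgG, 1.473 ± 1.814 in HET anti-CD40 and 0.827 ± 0.637 in the HET combination (SD, n = 4 each), and without replicate 3 of each group HET anti-CD40 stood at 0.566 and the HET combination at 0.512, below WT anti-PD1. HET anti-PD1 tumors stood at 0.103 ± 0.055 (n = 3). The log2 differences of Cd8a from HET IgG were 3.04 for anti-CD40 (exact p = 0.029, adjusted 0.17) and 2.63 for the combination (exact p = 0.029, adjusted 0.086). In WT tumors Cd8a was 0.121 ± 0.123 CPM after IgG (n = 5), 0.668 ± 0.522 after anti-PD1 (n = 4), 0.405 ± 0.418 after anti-CD40 (n = 3, 0.177 without replicate 2) and 0.324 ± 0.117 after the combination (n = 3), with exact p = 0.04 for anti-PD1, adjusted 0.21. Pdcd1 (ENSMUSG00000026285.7, chromosome 1, 94038305 to 94052553) stood at 0.855 ± 1.008 CPM in HET anti-CD40 (0.392 without replicate 3), 0.627 ± 0.267 in the HET combination and 0.064 ± 0.089 in HET IgG (n = 4 each), and 0.088 ± 0.096 in HET anti-PD1 (n = 3). In WT it was 0.106 ± 0.115 after IgG (n = 5), 0.288 ± 0.40 after anti-PD1 (n = 4, 0.101 without replicate 2), 0.418 ± 0.551 after anti-CD40 (0.10 without replicate 2) and 0.132 ± 0.048 after the combination (n = 3 each). HET anti-CD40 exceeded HET IgG by a log2 of 2.10 (exact p = 0.11), 1.40 without replicate 3. Its difference from WT anti-CD40 was 0.70 (exact p = 0.6), and 0.00 without HET anti-CD40 replicate 3 and 1.59 without WT anti-CD40 replicate 2. The HET combination exceeded HET IgG by a log2 of 2.43 and the WT combination by 1.70 (exact p = 0.029 for both, adjusted 0.086 and 0.17). Cd40 (ENSMUSG00000017652.12, chromosome 2, 165055627 to 165072948) was 2.069 ± 1.343 CPM in HET anti-CD40, 1.365 ± 0.752 in the HET combination and 0.415 ± 0.266 in HET IgG (n = 4 each), and the exact p was 0.057 for both differences from IgG (log2 difference 1.57 for the combination). It was 0.325 ± 0.121 in HET anti-PD1 (n = 3), and in WT 0.460 ± 0.156 after IgG (n = 5), 0.720 ± 0.563 after anti-PD1 (n = 4, 0.443 without replicate 1), 0.701 ± 0.450 after anti-CD40 and 0.460 ± 0.116 after the combination (n = 3 each). The difference between genotypes in the response to the combination was 2.02 for Pdcd1 (exact p = 0.032, adjusted 0.14) and 1.54 for Cd40 (exact p = 0.045, adjusted 0.14). Cd274 (ENSMUSG00000016496.7, chromosome 19, 29367455 to 29388095) was at 27.872 ± 9.251 CPM in WT IgG (n = 5), 38.378 ± 11.296 in WT anti-PD1 (n = 4), 21.149 ± 9.331 in WT anti-CD40 and 29.287 ± 2.489 in the WT combination (n = 3 each). In HET it was at 25.388 ± 12.654 after IgG (n = 4), 32.879 ± 1.703 after anti-PD1 (n = 3), 32.848 ± 16.724 after anti-CD40 and 29.456 ± 6.387 after the combination (n = 4 each), and no exact p was under 0.2. Means near the floor moved too: without WT IgG replicate 1 Cd8a was at 0.071 and Pdcd1 at 0.064, without HET IgG replicate 4 at 0.011 and 0.022, and Pdcd1 was at 0.037 without HET anti-PD1 replicate 1.

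**Figure D1:**
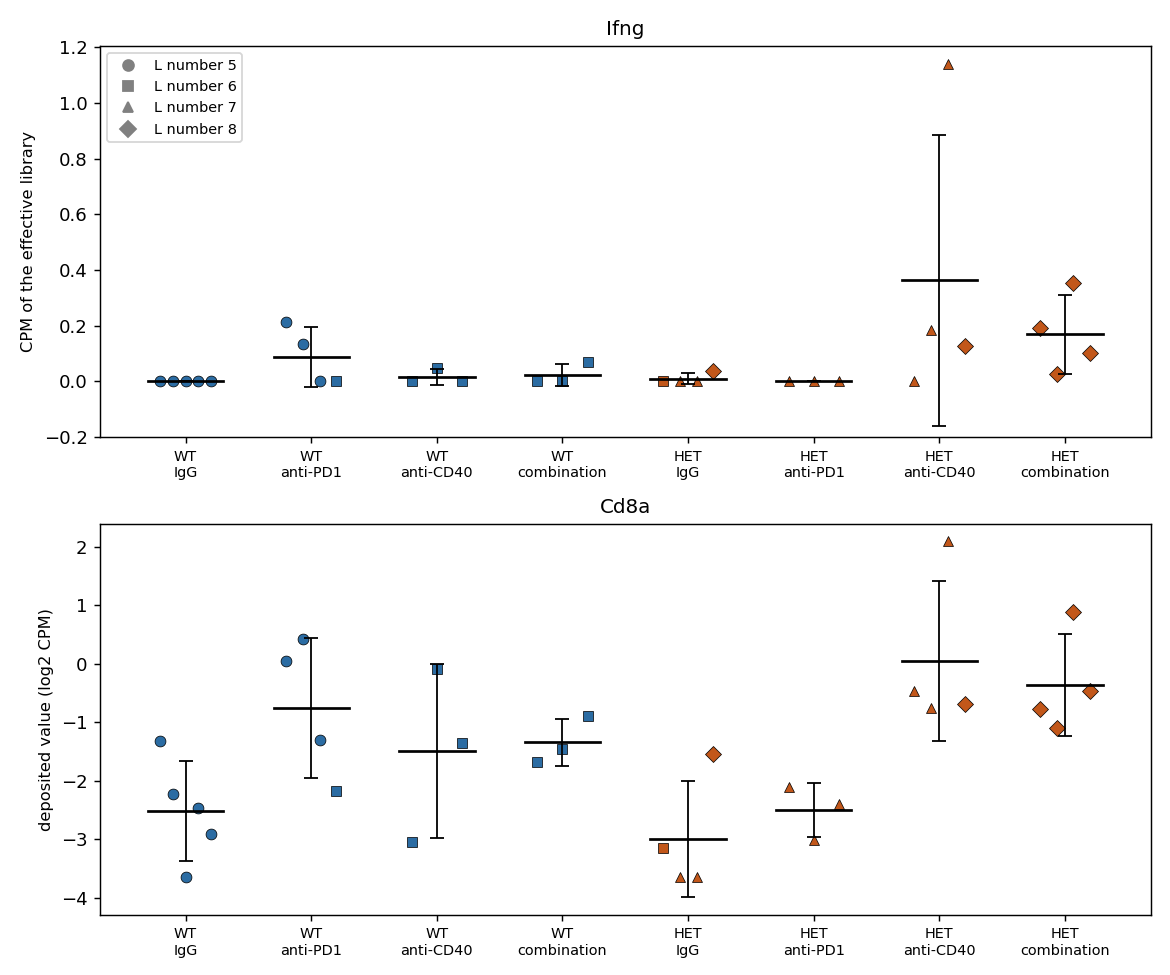
Ifng in CPM and Cd8a in log2 CPM (vertical axes) in each of the 30 libraries by group. Points are libraries, blue for WT and orange for HET, with circle, square, triangle and diamond for L numbers 5 to 8, and bars are the mean ± SD. The Cd8a means as drawn are 0.05 (log2) in HET anti-CD40 and -0.36 in the HET combination. In CPM, the means of Ifng and Cd8a in HET anti-CD40 are 0.363 and 1.473, and 0.104 and 0.566 without its replicate 3. Those of the HET combination are 0.168 and 0.827 CPM, and 0.107 and 0.512 without its replicate 3.

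Libraries differed widely in genes of skin and muscle, and these levels moved with the groups. The mean log2 value of 18 keratinocyte genes (keratins and other skin barrier genes) was 1.57 ± 3.78 in HET anti-CD40, 1.76 ± 2.40 in the HET combination and -1.72 ± 1.00 in HET IgG (SD, n = 4 each), and 2.36 ± 3.79 in WT anti-CD40 (n = 3) against -0.75 ± 2.66 in WT IgG (n = 5). The highest keratinocyte scores were 6.16 in WT anti-CD40 replicate 2, 5.04 in HET anti-CD40 replicate 4 and 4.63 in HET anti-CD40 replicate 3. The mean of 18 skeletal muscle genes was 3.30 ± 1.56 in HET anti-CD40, 3.01 ± 0.82 in the HET combination and 0.42 ± 2.54 in HET IgG (SD, n = 4 each), and -0.16 ± 1.37 in WT IgG (n = 5). The first principal component of all libraries held 44.9% of the variance, and 12 of its 50 leading genes were in the keratinocyte list. HET IgG replicate 2 stood apart in RNA composition. Its mitochondrially encoded genes took 6.53% of reads, 1554 genes of the table had no read, and its Xist value, a long noncoding RNA of female cells, was 1.23 (log2) against 3.07 to 5.77 in the other 29 libraries.

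**Figure D2:**
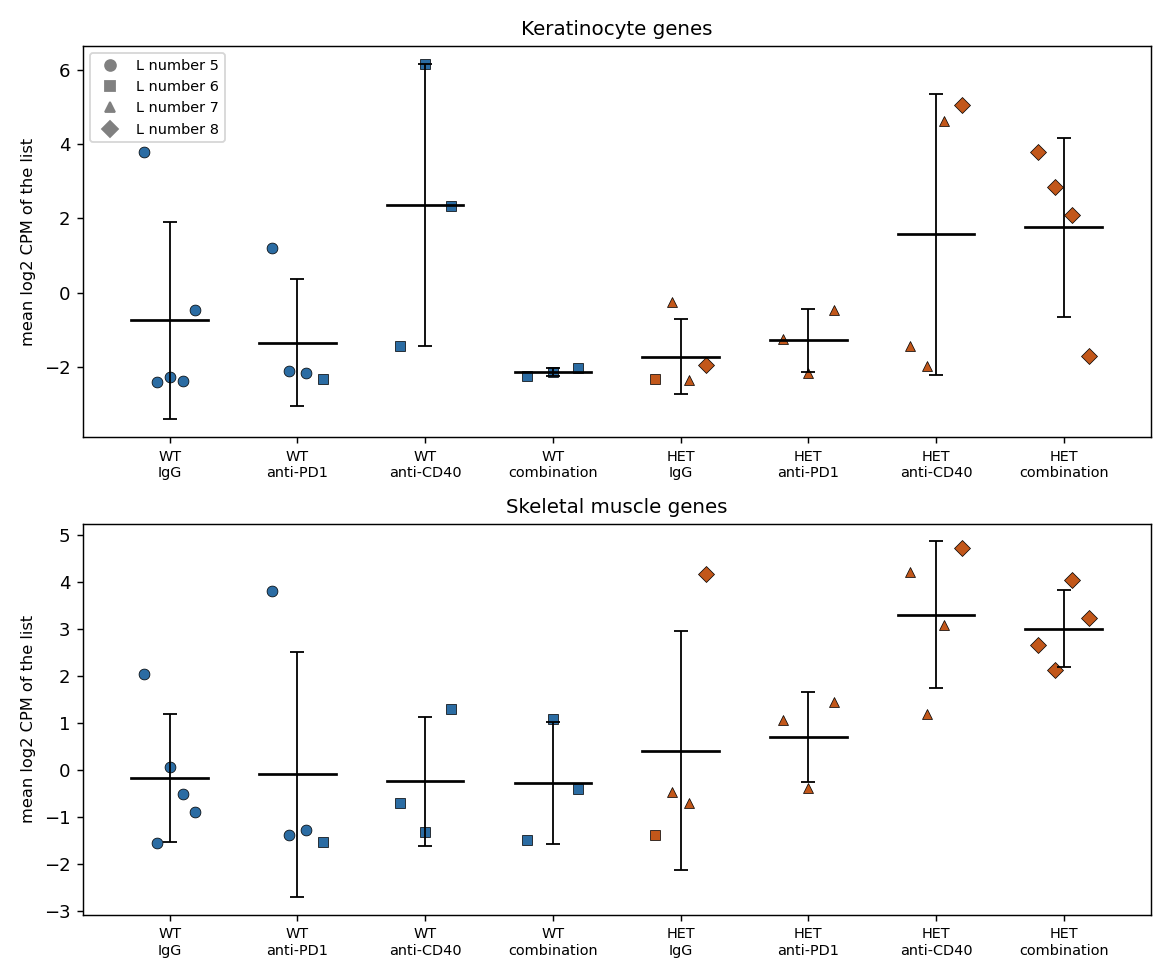
Mean log2 CPM of the keratinocyte list and of the skeletal muscle list (vertical axes) in each of the 30 libraries by group. Points are libraries, with colors for genotype and symbols for the L number, and bars are the mean ± SD. HET anti-CD40 and the HET combination have the highest muscle means, 3.30 and 3.01.

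Libraries also differ in their L number, which the labels do not explain. L5 holds all 5 WT IgG libraries and 3 of WT anti-PD1, and L6 holds 1 of WT anti-PD1, all of WT anti-CD40 and the WT combination and 1 of HET IgG. L7 holds 2 of HET IgG, all 3 of HET anti-PD1 and 3 of HET anti-CD40, and L8 holds 1 of HET IgG, 1 of HET anti-CD40 and all 4 of the HET combination. Values within 1 L number could be had for WT anti-PD1 (L5), for HET anti-PD1 and HET anti-CD40 (L7) and for the 2 WT groups given anti-CD40 (L6). No L number holds 2 libraries of each group for any other comparison, HET against WT included. A fit with the L number as a covariate then rests on the few groups that span numbers, and its values are given where they differ. In all 17 comparisons limma called 0 of 15002 genes, voom called 0 as well, and about 750 genes are expected at an unadjusted p under 0.05 by chance. Of the list calls made with the preset correlation, 9 in HET against WT under anti-CD40 held with an estimated correlation, and 0 did in the other 16 comparisons.

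Anti-PD1 in WT mice, against WT IgG (n = 4 and 5), asks what checkpoint blockade did in the unmodified host. Immune, stromal and vessel genes stood higher than other genes in these libraries. The adipocyte score was higher too, 2.08 ± 1.06 against 1.09 ± 0.78 (SD). The IFN-γ response list had 32 of 32 members higher, by a median log2 of 0.81, with Irgm1, an IFN-γ induced GTPase, at 0.33 ± 0.43 (SE). In the T cell list 8 of 8 members were higher (median 0.75), with Thy1 at 1.20 ± 0.52 and Tcf7 at 0.56 ± 0.27, and in the B cell list 3 of 4 (median 0.94), with Ebf1 at 1.03 ± 0.39 and Cd22 at 1.04 ± 0.58. Matrix genes of fibroblasts were higher in 22 of 22 members (median 1.07, Sparc 0.43 ± 0.25, Fn1 0.38 ± 0.45), and endothelial genes in 18 of 18 (median 0.49, Eng 0.16 ± 0.13, Vwf 0.31 ± 0.35). MHC class II genes, which present antigen to helper T cells, were higher in 8 of 9 (median 1.12, Ctss 1.13 ± 0.64, Cd74 1.16 ± 0.97), but without WT anti-PD1 replicate 1 the median was 0.38 and the call was lost.

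With the preset correlation 16 lists stood higher and 0 lower in WT anti-PD1, and the lists named had adjusted p from 2.2e-16 (fibroblast) to 0.0041 (B cell). With an estimated correlation their adjusted p lay between 0.11 and 0.27, and the exact p of their scores between 0.063 and 0.32. Adjusted over the list alone, 3 fibroblast genes passed, and 0 members of the other lists named. Single libraries moved several medians. Without WT anti-PD1 replicate 1 they were 0.22 (IFN-γ response), 0.48 (T cell) and 0.61 (fibroblast), without replicate 2 0.70 (MHC class II), and without replicate 3 0.31 (endothelial). Without replicate 4, the 1 library outside L5, the IFN-γ response, MHC class II and T cell medians were those within L5. Within L5 the medians were 1.42 (IFN-γ response), 1.76 (MHC class II), 1.19 (T cell), 1.16 (B cell), 1.36 (fibroblast) and 0.72 (endothelial). Among all genes, 413 had an unadjusted p under 0.05 by limma and 365 by voom, 854 with the L number as a covariate and 692 with the keratinocyte and muscle scores.

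Anti-CD40 in WT mice, against WT IgG (n = 3 and 5), went with skin genes, mainly in 1 library. All 18 keratinocyte genes were higher, by a median log2 of 2.93, with Sbsn at 0.72 ± 0.63 (SE) and Dsp, a gene of cell junctions, at 1.78 ± 1.13. That median was 0.95 without WT anti-CD40 replicate 2 and 4.83 without replicate 1. T cell genes were higher in 8 of 8 (median 0.78, Thy1 1.09 ± 0.57, Tcf7 0.40 ± 0.29), and inflammatory cytokine list genes in 15 of 17 (median 0.94, Nfkbia 0.27 ± 0.30, Nfkbiz -0.33 ± 0.39). Mitochondrially encoded genes were lower in 13 of 15 (median -0.60, mt-Co1 -1.04 ± 0.55, mt-Cytb -0.66 ± 0.41). The preset correlation placed 6 lists higher and 1 lower, and the adjusted p of these 4 ran from 1.2e-07 (keratinocyte) to 0.0012 (T cell), against 0.8 for each with an estimated correlation. Without WT anti-CD40 replicate 2 the T cell median was 0.41 and not called, the inflammatory median was 0.53 and Sbsn was at -0.33. Without WT IgG replicate 3 the inflammatory median was 0.59. Without WT IgG replicate 1 the inflammatory median was 0.77 and not called, with 4 lists called. The T cell and inflammatory medians were 2.66 and 2.06 with the L number as a covariate, and 0.46 and 0.60 with the keratinocyte and muscle scores, which gave -0.36 for the mitochondrial genes. Limma gave 777 genes at an unadjusted p under 0.05 and voom 582, and limma 509 with the L number and 164 with the keratinocyte and muscle scores as covariates. Library weights raised the limma count to 2548. For these lists 0 members passed when adjusted over the list alone.

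The combination in WT mice, against WT IgG (n = 3 and 5), showed lower blood cell genes and small shifts elsewhere. Red blood cell genes were lower in 8 of 8 members, by a median log2 of -2.94, with the hemoglobin gene Hbb-bs at -2.99 ± 1.36 (SE) and Bpgm at -0.37 ± 0.22. Neutrophil genes were lower in 11 of 11 (median -0.83), with S100a9 at -2.05 ± 1.33 and S100a8 at -1.78 ± 1.24. Type I interferon response genes were higher in 24 of 25 (median 0.36, Rsad2 -0.18 ± 0.33, Herc6 0.24 ± 0.29), and proliferation genes in 29 of 29 (median 0.13, Top2a 0.20 ± 0.26, Mki67 0.28 ± 0.37). Adjusted p with the preset correlation ran from 2.7e-15 (red blood cell) to 4.3e-06 (proliferation), and with an estimated one from 0.094 to 0.66. Without WT IgG replicate 4 the neutrophil median was -0.32, and without WT IgG replicate 5 the proliferation median was 0.02, neither called. The neutrophil median was -1.33 without WT IgG replicate 2 and -1.64 without WT combination replicate 3, and the proliferation median 0.24 and 0.08 without WT combination replicates 2 and 3. With the L number as a covariate the neutrophil median was -0.12, not called, the proliferation median -0.17, the red blood cell median -7.14 and the type I interferon median 1.22, and with the replicate number as a block the proliferation median was 0.04, not called. In all, 6 lists stood higher and 5 lower (17 called without WT combination replicate 1), and 62 genes had an unadjusted p under 0.05 by limma and 54 by voom, 251 with the L number as a covariate and 131 with the keratinocyte and muscle scores. No member passed when adjusted over the list alone.

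Anti-PD1 in HET mice, against HET IgG (n = 3 and 4), set few lists apart from the control. Mitochondrially encoded genes were lower in 15 of 15, by a median log2 of -0.66 (mt-Co1 -0.55 ± 0.57, mt-Cytb -0.49 ± 0.43, SE), and melanocyte genes in 12 of 16 (median -0.26, Dct -0.07 ± 0.20, Pmel -0.30 ± 0.29). Type I interferon response genes were higher in 25 of 25 (median 0.33, Rsad2 0.29 ± 0.35, Herc6 0.08 ± 0.31), and hypoxia and glycolysis genes in 19 of 21 (median 0.30, Aldoa -0.05 ± 0.27, Eno1 0.07 ± 0.23). These were the 4 lists called with the preset correlation, at adjusted p from 1.5e-10 to 0.042, against 0.71 to 0.92 with an estimated correlation. Within L7 the medians were -1.13 (mitochondrial), -0.36 (melanocyte), 0.13 (type I interferon, not called) and -0.03 (hypoxia), and 1 of the 2 IgG libraries of L7 is replicate 2, which stands apart in mitochondrial reads. As a covariate, the L number gave -1.10 (mitochondrial), 0.08 (type I interferon) and 0.12 (hypoxia), the last 2 not called, and the melanocyte median of -0.25 with the keratinocyte and muscle scores was not called either. Without HET IgG replicate 2 the mitochondrial median was -0.23, and -0.22 with library weights. Single libraries decided 3 of these calls. The type I interferon median was 0.11 without HET IgG replicate 1 and 0.20 without replicate 2, and the hypoxia median 0.22 without HET IgG replicate 1 and 0.09 without replicate 4. The melanocyte median was -0.16 and still called without HET IgG replicate 1. It was -0.02 without HET IgG replicate 2, -0.22 without replicate 3, -0.06 without HET anti-PD1 replicate 1 and -0.27 without replicate 3, and none of these was called. The number of lists called was 2 without HET IgG replicate 1 or 2, 8 without HET IgG replicate 4 and 7 without HET anti-PD1 replicate 2. There were 144 genes at an unadjusted p under 0.05 by limma and 134 by voom, 445 with the L number as a covariate and 421 with the keratinocyte and muscle scores. With library weights there were 1975, and limma called 1 gene. In these lists 0 members passed when adjusted over the list alone. Without HET anti-PD1 replicate 2, limma called 1 gene, and without HET IgG replicate 2 the values of Aldoa, Eno1 and Pmel were 0.35, 0.37 and 0.10.

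Anti-CD40 in HET mice, against HET IgG (n = 4 and 4), went with high IFN-γ response and antigen presentation scores. The IFN-γ response list had 32 of 32 members higher, by a median log2 of 2.15, and all 4 libraries, at scores of 3.28 to 5.41, lay above all 4 of IgG, at 0.93 to 2.97. Irgm1 stood at 1.22 ± 0.45 (SE). MHC class II genes were higher in 9 of 9 (median 2.96), with Cd74, the invariant chain, at 3.34 ± 1.03 and Ctss, a protease of antigen processing, at 2.52 ± 0.67. MHC class I genes were higher in 20 of 20 (median 1.51, B2m 0.85 ± 0.26, H2-D1 1.52 ± 0.39). Of 22 genes of cytotoxic and natural killer (NK) cells 6 passed the filter, and all 6 were higher (median 2.31). Among them the chemokine gene Ccl5 was at 2.28 ± 0.56 and Il2rb at 2.35 ± 0.68. Their mean score was low, -2.18 in HET IgG and 0.22 in HET anti-CD40 (log2), and the median was smaller with 1 added to the linear values.

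T cell genes were higher in 7 of 8 members in HET anti-CD40 tumors (median 1.53, Thy1 1.41 ± 0.55, Tcf7 -0.05 ± 0.28, SE), and macrophage genes in 21 of 21 (median 1.46, Lyz2 1.98 ± 0.65, Apoe 0.00 ± 0.26). Melanocyte genes were lower in 14 of 16 (median -0.43, Dct -0.41 ± 0.18, Pmel -0.52 ± 0.27), and mitochondrially encoded genes in 15 of 15 (median -1.15, mt-Co1 -1.65 ± 0.53, mt-Cytb -1.15 ± 0.40). Skin and muscle genes moved in the same libraries: keratinocyte genes were higher in 18 of 18 (median 3.35, Sbsn 1.24 ± 0.61, Dsp 2.05 ± 1.10) and muscle genes in 18 of 18 (median 2.73, Eno3 0.34 ± 0.22, Mylpf 1.46 ± 0.66). Single genes with high values, chosen after they were seen, were the integrin gene Itgal at 2.25 ± 0.48, Il18bp at 1.86 ± 0.41, the immunoproteasome gene Psmb8 at 3.12 ± 0.71 and Cd8a at 3.04 ± 0.71. Their adjusted p by limma was 0.16 for Itgal, Il18bp and Psmb8 and 0.17 for Cd8a.

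In HET anti-CD40 against HET IgG, 20 lists stood higher and 3 lower with the preset correlation, the 10 named at adjusted p from 4.2e-20 (IFN-γ response) to 0.00021 (melanocyte). With an estimated correlation their adjusted p lay between 0.14 and 0.25. The exact p was 0.029, the smallest that 4 against 4 libraries allow, for the IFN-γ, MHC class I, MHC class II, T cell, cytotoxic and macrophage scores, or 0.093 adjusted over the 26 lists. It was 0.057 for the melanocyte and mitochondrial scores, 0.086 for muscle and 0.2 for keratinocyte genes. By p adjusted over the list alone, 27 IFN-γ response, 20 MHC class I, 9 MHC class II, 6 cytotoxic, 4 T cell, 12 macrophage, 9 muscle and 12 mitochondrial genes passed, and 0 keratinocyte and melanocyte genes. Within L7 (3 against 2 libraries, of which 1 is HET IgG replicate 2) the medians were 2.55 (IFN-γ response), 1.46 (MHC class I), 3.37 (MHC class II), 2.38 (cytotoxic), 1.44 (T cell), 1.60 (macrophage), 1.60 (keratinocyte), 3.37 (muscle), -0.60 (melanocyte) and -1.57 (mitochondrial). With the keratinocyte and muscle scores as covariates the medians were 1.28 (IFN-γ response), 0.74 (MHC class I), 1.39 (MHC class II), 1.23 (cytotoxic), 0.29 (T cell), 0.59 (macrophage), -0.19 (melanocyte) and -0.72 (mitochondrial). The mitochondrial median was -0.84 without HET IgG replicate 2, and -0.61 with library weights, which give that library a weight of 0.11. Without HET anti-CD40 replicate 4 the keratinocyte median was 2.22. The melanocyte call was lost with quantile normalization and with library weights. Limma gave 2230 genes at an unadjusted p under 0.05 and voom 2172, but limma gave 462, fewer than chance gives, with the keratinocyte and muscle scores as covariates, 2499 with the L number and 1212 within L7. Without HET IgG replicate 4, limma called 1 gene.

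The combination in HET mice, against HET IgG (n = 4 and 4), also went with high interferon and antigen presentation scores. IFN-γ response genes were higher in 31 of 32, by a median log2 of 1.85 (Irgm1 1.13 ± 0.45, SE), and the 4 libraries scored 3.08 to 4.74, above all 4 of IgG. MHC class I genes were higher in 20 of 20 (median 1.24, B2m 0.96 ± 0.26, H2-D1 1.40 ± 0.39) and MHC class II genes in 9 of 9 (median 2.70, Ctss 2.26 ± 0.67, Cd74 3.29 ± 1.03). Cytotoxic and NK genes were higher in 6 of 6 (median 1.93, Ccl5 1.97 ± 0.56, Il2rb 1.75 ± 0.68), and T cell checkpoint and activation genes in 9 of 9 (median 0.93, Cd274 0.30 ± 0.35, Tnfrsf9 0.22 ± 0.55). Genes of alternatively activated macrophages were higher in 9 of 9 (median 2.12, Mrc1 1.16 ± 0.74, Arg1 0.96 ± 0.90).

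Adipocyte, skin and muscle genes moved in the HET combination tumors too. Adipocyte genes were higher in 14 of 14 (median 2.16), and the most abundant ones were Scd1, at 0.04 ± 0.30 (SE), and Pnpla2, at 0.08 ± 0.20, both within their error of 0. Keratinocyte genes were higher in 18 of 18 (median 3.60, Sbsn 0.81 ± 0.61, Dsp 1.84 ± 1.10), and muscle genes in 18 of 18 (median 2.42, Eno3 0.16 ± 0.22, Mylpf 1.31 ± 0.66). Chosen after they were seen, Casp1, the inflammasome protease gene, stood at 2.66 ± 0.55 and the interferon-induced gene Mndal at 2.91 ± 0.55 (adjusted p = 0.19 by limma for both), and Ubd at 3.88 ± 0.89 and Cd8a at 2.63 ± 0.71 (0.25 for both). Without HET IgG replicate 4 limma called 6 genes, with Mndal at 3.46 and Casp1 at 3.11 among the named genes that then passed.

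In the HET combination against HET IgG, 18 lists stood higher and 4 lower with the preset correlation, and the adjusted p of those named ran from 1.1e-21 (IFN-γ response) to 0.00044 (checkpoint). With an estimated correlation it lay between 0.11 and 0.18. The exact p was 0.029 (adjusted 0.074) for the IFN-γ, MHC class I, MHC class II, cytotoxic, checkpoint, alternatively activated macrophage and adipocyte scores, 0.057 for keratinocyte and 0.14 for muscle genes. Adjusted over the list alone, 26 IFN-γ response, 19 MHC class I, 9 MHC class II, 5 cytotoxic, 5 alternatively activated macrophage and 10 adipocyte genes passed, and 0 checkpoint, keratinocyte and muscle genes. With the keratinocyte and muscle scores as covariates the medians were 1.09 (IFN-γ response), 0.56 (MHC class I), 1.19 (MHC class II), 0.81 (cytotoxic), 1.11 (adipocyte) and 0.40 (checkpoint, not called). Medians with the L number as a covariate were 0.42 (checkpoint), 2.05 (keratinocyte), 1.03 (adipocyte) and -0.15 (muscle), and the muscle median was 3.65 without HET IgG replicate 4. The adipocyte median was 0.48 with the stricter filter, and quantile normalization gave 0.96 for cytotoxic and 0.35 for checkpoint genes. Limma gave 1472 genes at an unadjusted p under 0.05 and voom 1344, but limma gave 161 with the L number as a covariate and 751 with the keratinocyte and muscle scores.

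**Figure D3:**
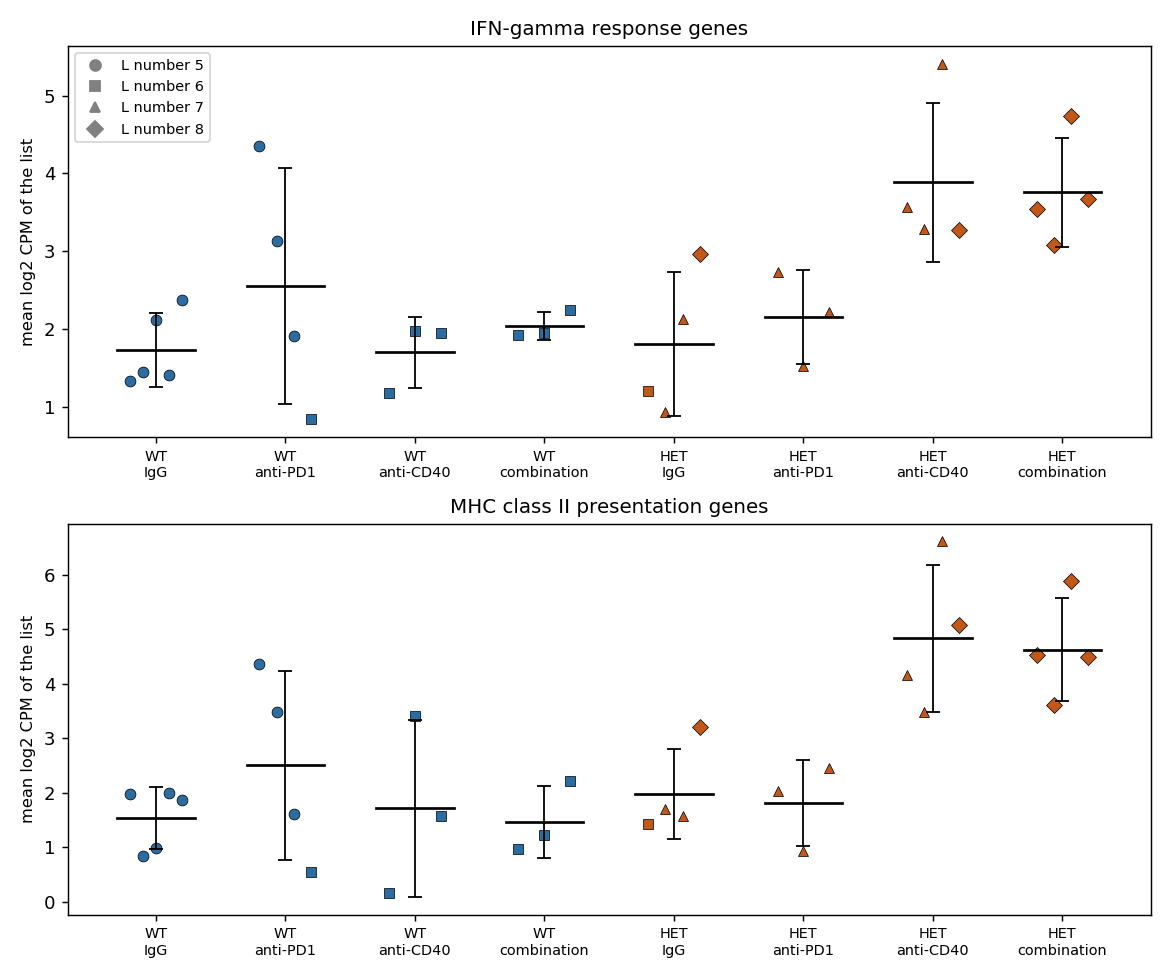
Mean log2 CPM of the IFN-γ response list and of the MHC class II list (vertical axes) in each of the 30 libraries by group. Points are libraries, with colors for genotype and symbols for the L number, and bars are the mean ± SD. The IFN-γ scores of the 8 HET libraries given anti-CD40, alone or in the combination, lie between 3.08 and 5.41, and the 4 of HET IgG between 0.93 and 2.97.

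HET against WT under IgG (n = 4 and 5) asks what the allele did without immunotherapy, and few lists stood apart. IFN-γ response genes had a median log2 of 0.06 and were not called. Neutrophil genes were lower in 11 of 11 (median -1.11, S100a9 -2.14 ± 1.22, S100a8 -1.84 ± 1.14, SE) and inflammatory cytokine genes in 14 of 17 (median -0.57, Nfkbia 0.04 ± 0.27, Nfkbiz -0.43 ± 0.36). Macrophage genes were higher in 19 of 21 (median 0.37, Apoe 0.22 ± 0.24, Lyz2 0.08 ± 0.61). Adjusted p was 2.5e-05, 0.00035 and 0.0049 for these lists with the preset correlation, and 0.72 to 0.87 with an estimated one. With the L number as a covariate the medians were -0.04 (neutrophil), 0.68 (inflammatory) and 2.13 (macrophage), and with the replicate number as a block the inflammatory median was -0.36, not called. Without WT IgG replicate 4 the neutrophil median was -0.35 and the inflammatory median -0.40, neither called. The inflammatory call was also lost without WT IgG replicate 5 (-0.36) or HET IgG replicate 2 (-0.31), and the macrophage call without WT IgG replicate 3 (0.11) or HET IgG replicate 4 (0.27), and that median was 0.79 without WT IgG replicate 4 and 0.58 without HET IgG replicate 2. With the preset correlation 3 lists stood higher and 3 lower, and 12 were called without WT IgG replicate 3 and 3 without WT IgG replicate 4. Genes at an unadjusted p under 0.05 numbered 310 by limma and 207 by voom, 98 with the L number as a covariate and 1136 with the keratinocyte and muscle scores. In these lists none passed when adjusted over the list alone.

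Under anti-PD1, HET tumors (n = 3) had lower stromal and T cell genes than WT tumors (n = 4). Fibroblast genes were lower in 22 of 22, by a median log2 of -1.35 (Sparc -0.52 ± 0.28, Fn1 -0.76 ± 0.51, SE), and T cell genes in 7 of 8 (median -0.94, Thy1 -1.32 ± 0.59, Tcf7 0.08 ± 0.30). Adjusted p was 9.6e-18 and 0.00062 with the preset correlation and 0.22 and 0.3 with an estimated one, and 2 fibroblast and 0 T cell genes passed when adjusted over the list alone. Under the L number as a covariate the medians were -0.08 (fibroblast, not called) and 0.36 (T cell). In all, 1 list stood higher and 17 lower, but 8 were called without WT anti-PD1 replicate 1, without which the T cell median was -0.67 and not called. It was -0.57 without HET anti-PD1 replicate 2. Limma gave 321 genes at an unadjusted p under 0.05 and voom 297, and limma 51 with the L number as a covariate and 773 with the keratinocyte and muscle scores.

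Under anti-CD40, HET tumors (n = 4) exceeded WT tumors (n = 3) in IFN-γ response and antigen presentation genes, and these calls held with an estimated correlation. IFN-γ response genes were higher in 32 of 32, by a median log2 of 2.23, with Irgm1 at 1.35 ± 0.49 (SE), and the group scores were 3.89 ± 1.02 and 1.70 ± 0.46 (SD). MHC class II genes were higher in 9 of 9 (median 3.43, Ctss 2.03 ± 0.73, Cd74 4.09 ± 1.11), and MHC class I genes in 20 of 20 (median 1.38, B2m 0.98 ± 0.28, H2-D1 1.30 ± 0.42). Cytotoxic genes were higher in 6 of 6 (median 1.87, Ccl5 1.19 ± 0.60, Il2rb 1.92 ± 0.73) and macrophage genes in 19 of 21 (median 1.29, Apoe 0.26 ± 0.28, Lyz2 1.25 ± 0.70). Muscle genes moved as well, higher in 17 of 18 (median 3.81, Eno3 -0.08 ± 0.23, Mylpf 1.53 ± 0.71), while the keratinocyte median was -0.77 and not called.

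Conventional dendritic cell genes were also higher under anti-CD40 in HET than in WT tumors in 8 of 10 (median 0.62, Irf4 -0.49 ± 0.50, Naaa 0.62 ± 0.29, SE), activated dendritic cell and CD40 response genes in 14 of 18 (median 0.40, Fscn1 -0.44 ± 0.16, Bcl2l1 0.25 ± 0.32), and endothelial genes in 18 of 18 (median 0.46, Eng 0.25 ± 0.15, Vwf 0.40 ± 0.40). For the 9 lists of this comparison the adjusted p with an estimated correlation was 0.0074 for the IFN-γ response, MHC class I and MHC class II, 0.025 for cytotoxic, 0.026 for muscle, 0.037 for conventional dendritic cell and 0.047 for macrophage, activated dendritic cell and endothelial genes. With the preset correlation these ran from 9.4e-50 (IFN-γ response) to 2.3e-05 (conventional dendritic cell), with 17 lists higher and 4 lower. The exact p of the score was 0.029 for the IFN-γ response, the smallest that 4 against 3 libraries allow, or 0.37 adjusted over the 26 lists, and 0.057 to 0.2 for the other 8. At the level of genes, adjusted over the list alone, 26 IFN-γ response, 20 MHC class I, 9 MHC class II, 3 cytotoxic, 2 conventional dendritic cell and 13 muscle genes passed. With the L number as a covariate the medians were 1.46 (IFN-γ response), 0.84 (MHC class I), 2.59 (MHC class II), 1.20 (muscle), 0.22 (activated dendritic cell, not called) and 0.08 (endothelial, not called), and with the stricter filter the activated dendritic cell median was 0.25, not called. With the keratinocyte and muscle scores as covariates the medians were 1.42 (IFN-γ response), 1.16 (MHC class I), 2.54 (MHC class II) and 0.26 (endothelial). Without HET anti-CD40 replicate 3 the medians were 1.17 (cytotoxic), 0.36 (conventional dendritic cell) and 0.22 (activated dendritic cell). The conventional dendritic cell median was 1.07 without WT anti-CD40 replicate 2, and the activated one 0.63 without HET anti-CD40 replicate 1. Il18bp, at 2.25 ± 0.45, and Ciita, the regulator of MHC class II genes, at 3.60 ± 0.93 (SE), had limma adjusted p of 0.45 and 0.48. Limma gave 575 genes at an unadjusted p under 0.05 and voom 605, and limma 201 with the L number as a covariate and 599 with the keratinocyte and muscle scores.

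Under the combination, HET tumors (n = 4) again exceeded WT tumors (n = 3) in interferon and antigen presentation genes. IFN-γ response genes were higher in 31 of 32, by a median log2 of 1.72 (Irgm1 0.82 ± 0.49, SE), MHC class I genes in 20 of 20 (median 1.24, B2m 1.03 ± 0.28, H2-D1 1.41 ± 0.42) and MHC class II genes in 9 of 9 (median 2.94, Ctss 2.46 ± 0.73, Cd74 4.00 ± 1.11). Conventional dendritic cell genes were higher in 9 of 10 (median 1.20, Irf4 0.00 ± 0.50, Naaa 0.76 ± 0.29). Muscle genes were higher in 18 of 18 (median 3.65, Eno3 0.27 ± 0.23, Mylpf 1.73 ± 0.71), and keratinocyte genes had a median of 4.12. Casp1 stood at 2.89 ± 0.60 and the class II gene H2-Aa at 4.03 ± 1.08 (limma adjusted p = 0.37 and 0.66). The adjusted p of the 5 lists with members named ran from 3e-19 (MHC class I) to 6.8e-06 (conventional dendritic cell) with the preset correlation, which placed 18 lists higher and 1 lower, and from 0.076 to 0.15 with an estimated one. Their exact p was 0.029 each, adjusted 0.093, and 17 IFN-γ response, 16 MHC class I, 9 MHC class II, 6 conventional dendritic cell and 12 muscle genes passed when adjusted over the list alone. Under the L number as a covariate the medians were 0.92 (IFN-γ response), 0.51 (MHC class I), 1.79 (MHC class II) and -1.36 (muscle), and with the keratinocyte and muscle scores as covariates 0.73, 0.48, 1.61 and 0.59 for the IFN-γ response, MHC class I, MHC class II and conventional dendritic cell genes. The stricter filter gave 1.04 for the IFN-γ response and 0.38 for conventional dendritic cell genes. Limma gave 834 genes at an unadjusted p under 0.05 and voom 778, but limma gave 79 with the L number as a covariate and 185 with the keratinocyte and muscle scores.

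The combination against each single antibody asks what the second antibody added. In WT mice the combination (n = 3) stood below anti-PD1 alone (n = 4) in IFN-γ response genes, lower in 29 of 32 (median log2 -0.51, Irgm1 0.00 ± 0.49, SE), and in endothelial genes, lower in 17 of 18 (median -0.36, Eng -0.12 ± 0.15, Vwf -0.76 ± 0.40). Adjusted p was 8e-05 and 2.1e-08 with the preset correlation, 0.47 and 0.23 with an estimated one, and the exact p was 0.69 and 0.2. Without WT anti-PD1 replicate 1 the IFN-γ median was 0.08, and with the L number as a covariate the medians were 0.97 and 0.13. The IFN-γ median was -1.0 without WT anti-PD1 replicate 4. The endothelial median was -0.14 and -0.56 without WT anti-PD1 replicates 3 and 4, and -0.18 without WT combination replicate 1. There 1 list stood higher and 18 lower, and 8 were called without WT anti-PD1 replicate 1. Against WT anti-CD40 (n = 3 and 3, all L6), the combination was lower in keratinocyte genes, 18 of 18 (median -3.93, Sbsn -1.31 ± 0.70, Dsp -2.41 ± 1.27), and in neutrophil genes, 11 of 11 (median -2.02, S100a9 -4.30 ± 1.49, S100a8 -4.18 ± 1.39). Adjusted p was 1e-11 and 1.3e-06 with the preset correlation and 0.75 for both with an estimated one, and the exact p was 0.1 for both, the smallest that 3 against 3 libraries allow. Adjusted over the list alone, 11 keratinocyte and 3 neutrophil genes passed, and 0 IFN-γ response and endothelial genes in the first comparison. In the second, 1 list stood higher and 4 lower, and 10, 8 and 12 were called without WT anti-CD40 replicate 2, WT anti-CD40 replicate 3 and WT combination replicate 3. Without WT anti-CD40 replicate 2 the medians were -2.03 (keratinocyte) and -1.32 (neutrophil), and Sbsn was at -0.26. The neutrophil median was -1.26 with the keratinocyte and muscle scores as covariates. Genes at an unadjusted p under 0.05 numbered 281 by limma and 236 by voom against anti-PD1, and 799 and 570 against anti-CD40. They numbered 44 and 725 with the L number as a covariate, and 476 and 125 with the keratinocyte and muscle scores.

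In HET mice the combination (n = 4) stood above anti-PD1 alone (n = 3) in most lists and apart from anti-CD40 alone (n = 4) in few. Against anti-PD1, IFN-γ response genes were higher in 30 of 32 (median log2 1.69, Irgm1 0.84 ± 0.49, SE), MHC class II genes in 9 of 9 (median 2.97, Ctss 1.99 ± 0.73, Cd74 3.56 ± 1.11), and plasma cell genes, of antibody-secreting cells, in 6 of 7 (median 2.29, Sdc1 0.28 ± 0.32, Irf4 -0.21 ± 0.50). Skin, muscle and fat genes were higher too, with medians of 3.40 (keratinocyte), 2.21 (muscle) and 1.69 (adipocyte). With the keratinocyte and muscle scores as covariates the IFN-γ median was 0.89 and the MHC class II median 1.80. Adjusted p was 4.3e-12, 2e-09 and 0.0025 with the preset correlation and 0.21 for each with an estimated one, and the exact p was 0.029 for each (adjusted 0.068). When adjusted over the list alone, 8 MHC class II, 3 plasma cell and 0 IFN-γ response genes passed. The plasma cell median was -0.11 with the L number as a covariate and 0.63 with the keratinocyte and muscle scores, neither called, and 1.37 without HET anti-PD1 replicate 2. Against anti-PD1, 19 lists stood higher and 2 lower, with 1765 genes at an unadjusted p under 0.05 by limma and 1804 by voom, but 160 with the L number as a covariate and 815 with the keratinocyte and muscle scores. There limma called 1 gene without HET anti-PD1 replicate 2, 54 with the compared groups alone and 1438 with library weights. Against anti-CD40 the IFN-γ response median was -0.12 and not called. Mitochondrially encoded genes were higher in 14 of 15 (median 0.41, mt-Co1 0.41 ± 0.53, mt-Cytb 0.29 ± 0.40), and hypoxia genes lower in 21 of 21 (median -0.21, Aldoa -0.14 ± 0.25, Eno1 -0.13 ± 0.21), at adjusted p of 2.3e-05 and 3.9e-05 with the preset correlation and 0.89 for both with an estimated one. The hypoxia median was -0.04, not called, and the mitochondrial median 0.95 with the L number as a covariate, and 0 members of either list passed when adjusted over the list alone. Here 2 lists stood higher and 4 lower, with 92 genes at an unadjusted p under 0.05 by limma and 110 by voom, 774 with the L number as a covariate and 339 with the keratinocyte and muscle scores. Over the libraries left out, the mitochondrial median was 0.20 without HET anti-CD40 replicate 3 or 4, 0.22 without combination replicate 4, 0.74 without HET anti-CD40 replicate 2 and 0.69 without combination replicate 1. The hypoxia median was -0.40 and -0.10 without HET anti-CD40 replicates 1 and 2. The number of lists called was 10 without HET anti-CD40 replicate 1 or 4, 14 without HET anti-CD40 replicate 2 or combination replicate 3, and 3 without combination replicate 1.

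The interactions ask whether HET and WT tumors differed in their response. For anti-CD40, IFN-γ response genes had a larger response in HET in 30 of 32 (median log2 1.94, Irgm1 1.33 ± 0.65, SE), MHC class II genes in 9 of 9 (median 2.82, Ctss 1.76 ± 0.97, Cd74 3.48 ± 1.47), and regulatory T cell genes in 5 of 5 (median 0.72, Lrrc32 0.63 ± 0.51, Ikzf2 0.40 ± 0.57). The regulatory T cell score fell in WT, from 1.06 to 0.81, and rose in HET, from 0.60 to 1.14. Muscle genes had a larger response in HET as well, by a median of 3.03. Adjusted p was 9.2e-27, 8e-12 and 0.0062 with the preset correlation and 0.066 for each with an estimated one, and the exact p was 0.055, 0.13 and 0.033, all 0.56 when adjusted. With the L number as a covariate the medians were -0.20, -0.29 and 0.43 (not called), and without HET IgG replicate 2 the regulatory T cell median was 0.46, not called. When adjusted over the list alone, 10 IFN-γ response, 2 MHC class II and 0 regulatory T cell genes passed. Of the lists 15 stood higher and 3 lower (9 called without WT anti-CD40 replicate 1), and 334 genes had an unadjusted p under 0.05 by limma and 249 by voom, 93 with the L number as a covariate and 294 with the keratinocyte and muscle scores.

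For the combination, the response in HET was larger for IFN-γ response genes in 31 of 32 (median log2 1.72, Irgm1 0.80 ± 0.65, SE) and MHC class II genes in 9 of 9 (median 2.79, Ctss 2.19 ± 0.97, Cd74 3.38 ± 1.47). Neutrophil genes moved apart, in 11 of 11 (median difference 2.21, S100a9 4.61 ± 1.85, S100a8 4.25 ± 1.73): from IgG to the combination their score fell in WT, from 0.17 to -0.95, and rose in HET, from a low -1.16 to 0.57. Adjusted p was 2.7e-12, 2.4e-09 and 2.7e-09 with the preset correlation and 0.24, 0.18 and 0.18 with an estimated one, and the exact p was 0.068, 0.068 and 0.013, all 0.18 when adjusted. With the L number as a covariate the medians were -0.71, -0.95 and 1.36, and with the keratinocyte and muscle scores those of the first 2 were 0.74 and 0.93. The neutrophil median was 1.41 without WT IgG replicate 4. Adjusted over the list alone, 7 MHC class II, 5 neutrophil and 0 IFN-γ response genes passed, with 15 lists higher and 3 lower, among them keratinocyte (median 4.72), muscle (2.73) and adipocyte genes (2.38) higher. For anti-PD1, fibroblast genes had a smaller response in HET in 22 of 22 (median -1.17, Sparc -0.43 ± 0.37, Fn1 -0.05 ± 0.68), their score going from 3.63 to 4.68 in WT and from 3.42 to 3.33 in HET, at an adjusted p of 1.7e-10 with the preset and 0.33 with an estimated correlation and an exact p of 0.28, and 2 of them passed when adjusted over the list alone. The fibroblast median was -0.64 and -1.76 without WT IgG replicates 3 and 4, -0.53 without WT anti-PD1 replicate 1, -0.61 without HET IgG replicate 4 and -0.66 without HET anti-PD1 replicate 2. In that interaction 1 list stood higher and 13 lower, and 8 and 9 were called without WT anti-PD1 replicate 1 and HET IgG replicate 4. Genes at an unadjusted p under 0.05 numbered 525 by limma and 321 by voom for the combination, and 155 and 149 for anti-PD1. They numbered 84 and 273 with the L number as a covariate, and 351 and 466 with the keratinocyte and muscle scores.

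**Figure D4:**
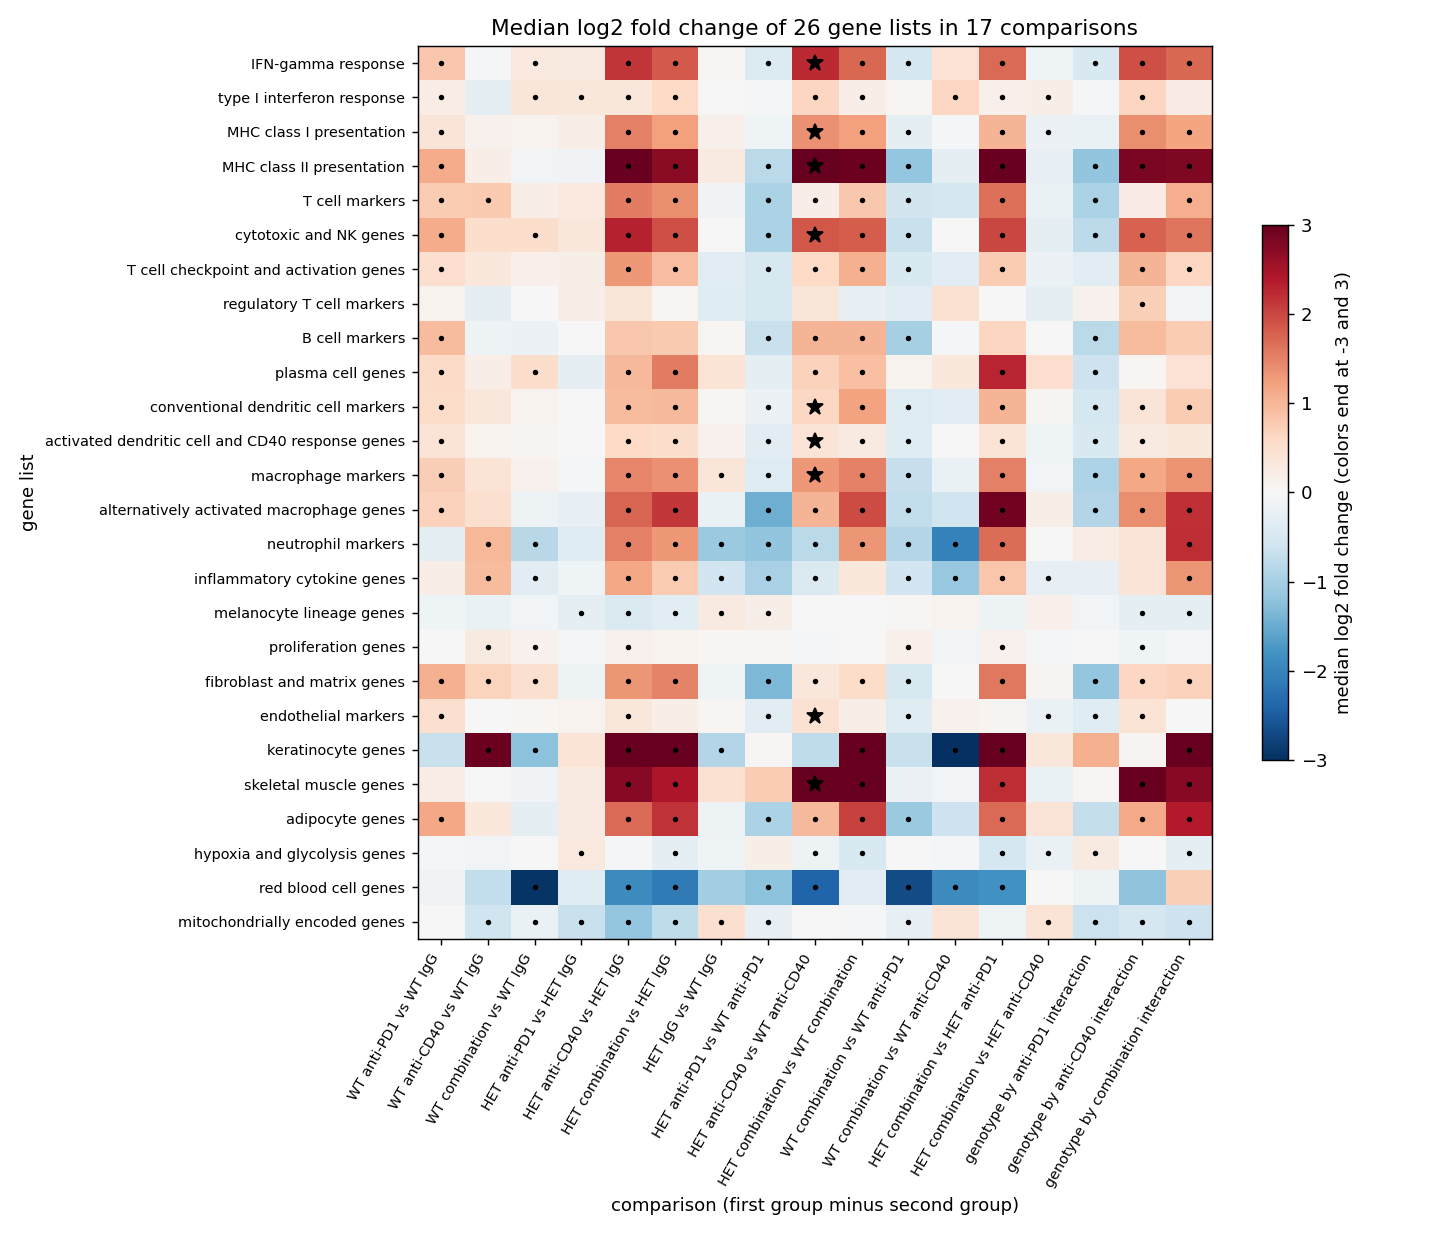
Median log2 difference of the members of each of the 26 gene lists (rows) in each of the 17 comparisons (columns), as a color scale. Dots mark lists called with the preset correlation and stars those called with an estimated correlation. The 9 stars are all in HET against WT under anti-CD40.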

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

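The tests of skin and muscle, of host cells, of the L number and of HET IgG replicate 2 were chosen only after the result was seen, and so were the exact tests of list scores, while the counts over other splits of the samples were planned.

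In HET tumors given anti-CD40, alone or in the combination, the IFN-γ response score exceeded HET IgG by 2.08 ± 0.61 and 1.95 ± 0.61 (log2, SE), with MHC class I and II genes. More host cells of all or some types stay open. The 6 IFN-γ and MHC differences exceeded the endothelial one by 1.09 ± 0.39 to 2.45 ± 0.75 (lowest 2.8 SE). This cannot decide: endothelial genes may rise less than host cells. Xist, low in IgG replicate 2, differed by 0.81 ± 0.65 and 0.76 ± 0.65. Skin or muscle carried over cannot be told apart from a response. With both scores as covariates the 6 differences were 0.65 ± 0.36 to 1.45 ± 0.70 (lowest 1.8 SE). A batch marked by the L number stays open too. In L7 the IFN-γ difference for anti-CD40 was 2.56 (3 against 2 libraries, IgG replicate 2 at 0.93). The 95% interval was -0.52 to 5.64, exact p = 0.1 (the smallest possible). In L8 the scores were 2.97 (IgG), 3.28 (anti-CD40, 1 library each) and 3.08 to 4.74 (combination). No L number holds both genotypes given anti-CD40. A genotype-dependent host response, the biological candidate, stays untested.

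HET IgG replicate 2 had a ratio of total to effective library size of 1.30 (others of its group 0.96 to 1.02), a log2 value of Xist of 1.23 and 1554 genes without a read. Shallow sequencing is argued against, because the other HET IgG libraries thinned to its 21.85 M reads had at most 936 genes without a read. Fewer host cells stay open. Xist less the mean of 4 host cell list scores differed from the other HET IgG libraries by a log2 of -3.37, against an SD of 0.23 between them. The test cannot decide, because it takes the 4 scores to fall as far as Xist. List genes that tumor cells also make, or that lie near the floor, would fall less. All 4 scores were lower in this library, by -0.25 (T cell) to -1.14 (fibroblast). No biological explanation was tested, and RNA degradation or loss of nuclear RNA was not tested either.

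Keratinocyte and muscle genes differed between libraries of the same group, and the scores of WT anti-PD1 replicate 1 (keratinocyte 1.21, muscle 3.81) and HET IgG replicate 4 (muscle 4.17) lay far from the others of their groups. Neighboring skin or muscle in the sample is a candidate explanation that stays open: within groups, members of the muscle list had a median correlation of 0.88 and those of the keratinocyte list 0.90, but the spread of the list means already requires this, whatever its source. The labels do not say how tumors were dissected, and no biological explanation was tested.

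Other libraries far from the rest of their group were found by Dixon's bound, which chance passes in about 1 of 20 groups: 14 of 183 tested passed, against 9.2 expected. HET anti-CD40 replicate 3 had an IFN-γ response score of 5.41 and a Cd8a value of 2.09 (log2), and HET anti-CD40 replicate 2 a fibroblast score of 4.08. HET IgG replicate 4 had an MHC class II score of 3.21. The B cell score was -0.65 in WT anti-PD1 replicate 4 and -0.76 in HET combination replicate 2. The melanocyte score was 8.51 in WT anti-PD1 replicate 1, the proliferation score 6.55 in WT IgG replicate 5, and the Pdcd1 value 0.15 in HET combination replicate 3.

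Between genotypes, 8 of 78 list scores differed in their response at an exact p under 0.05, against 3.9 expected by chance, and none passed adjustment over the 26 lists (lowest 0.56 for anti-CD40 and 0.18 for the combination). For anti-CD40 the regulatory T cell score differed in its response by 0.80, falling in WT and rising in HET (exact p = 0.033). For the combination the differences were 1.54 for cytotoxic genes (exact p = 0.044), 0.97 for checkpoint genes (exact p = 0.049), 0.63 for regulatory T cell genes (exact p = 0.014) and 1.29 for conventional dendritic cell genes (exact p = 0.047). They were 2.85 for neutrophil genes (exact p = 0.013), 4.87 for keratinocyte genes (exact p = 0.044) and 2.35 for adipocyte genes (exact p = 0.046). The checkpoint and regulatory T cell lists share 4 genes.

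For each comparison, other splits of the same libraries into groups of the same sizes were counted, first for genes at an unadjusted p under 0.05 and then for lists called with the preset correlation. Chance was excluded by none of these counts. For HET anti-CD40 against IgG, 7 of 35 splits gave at least the real 2230 genes (highest other 5305) and 2 of 35 the real 23 lists (highest other 23). For the HET combination against IgG, 10 of 35 gave 1472 genes (4409) and 3 of 35 gave 22 lists (24). For HET anti-PD1 they were 34 of 35 for 144 genes (3024) and 25 of 35 for 4 lists (12). In WT, anti-PD1 had 65 of 100 for 413 genes (1799) and 26 of 100 for 16 lists (21), anti-CD40 22 of 56 for 777 genes (5321) and 41 of 56 for 7 lists (24), and the combination 53 of 56 for 62 genes (1060) and 23 of 56 for 11 lists (17). HET against WT had 85 of 100 for 310 genes (3579) and 77 of 100 for 6 lists (18) under IgG, and 22 of 35 for 321 genes (1795) and 12 of 35 for 18 lists (24) under anti-PD1. Under anti-CD40 it had 16 of 35 for 575 genes (6727) and 2 of 35 for 21 lists (21), and under the combination 3 of 35 for 834 genes (1252) and 4 of 35 for 19 lists (19).

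The combination against anti-PD1 had 25 of 35 for 281 genes (947) and 9 of 35 for 19 lists (24) in WT, and 2 of 35 for 1765 genes (2136) and 3 of 35 for 21 lists (23) in HET. Against anti-CD40 in HET it had 22 of 35 for 92 genes (5189) and 32 of 35 for 6 lists (20). In WT the 10 splits are too few for a share under 0.05: 4 gave 799 genes (highest other 1433) and 7 gave 5 lists (highest other 16). The interactions had 91 of 100 for 155 genes (2777) and 17 of 100 for 14 lists (25) with anti-PD1, 66 of 100 for 334 genes (6193) and 13 of 100 for 18 lists (23) with anti-CD40, and 38 of 100 for 525 genes (3153) and 11 of 100 for 18 lists (22) with the combination. Some of these other splits called many genes, which points to a structure of the samples. The most was 4937 adjusted calls among the libraries of HET and WT anti-CD40, when the 3 with the highest keratinocyte scores were set against the rest.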

How the results depend on the processing

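The fits with voom and those with keratinocyte and muscle scores as covariates were chosen after the data were seen. So were all alternatives for the list tests other than the estimated correlation, the L number as a covariate and the replicate block. Gene calls stayed at 0 in every comparison with no filter, the stricter filter, 1 added, quantile normalization, no trend, voom, the L number, the replicate block, within 1 L number and the keratinocyte and muscle scores. With library weights limma called 1 gene (HET anti-PD1 against IgG), 47 (HET combination against IgG), 2 and 6 (HET against WT under anti-CD40 and the combination), 253 (WT combination against anti-CD40) and 1438 (HET combination against anti-PD1). These weights also gave more genes at an unadjusted p under 0.05 in every comparison but WT anti-PD1 against IgG, at 288 against 413. With the compared groups alone limma called 54 genes in HET combination against anti-PD1. Leaving out 1 library gave 0 to 1 gene for HET anti-PD1 and HET anti-CD40 against IgG and for HET combination against anti-PD1, 0 to 6 for HET combination against IgG, and 0 in the others. The cause was not tested for any change in this part unless it is given.

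Lists called with an estimated correlation were 9 for HET against WT under anti-CD40 and 0 in the other 16 comparisons, since members correlate. The stricter filter, which leaves fewer genes, gave 3, 6, 13 and 13 lists for WT anti-CD40, WT combination, HET anti-CD40 and HET combination against IgG, 8, 11 and 9 for HET against WT under anti-PD1, anti-CD40 and the combination, 2 for WT combination against anti-CD40, 10 for HET combination against anti-PD1 and 10 for the interaction with the combination. The L number gave 22, 21 and 2 for WT anti-CD40, WT combination and HET anti-PD1 against IgG, 20 and 10 for HET against WT under IgG and anti-PD1, 16 for HET combination against anti-CD40 and 5 for the interaction with anti-CD40. The keratinocyte and muscle scores gave 10 for HET combination against IgG, 13 for HET against WT under anti-CD40, 12 for the WT combination against anti-CD40, 12 and 3 for the HET combination against anti-PD1 and anti-CD40, and 6 for the interaction with the combination. Library weights gave 12 for HET anti-PD1 against IgG, 11 for HET against WT under anti-PD1, 12 and 3 for the WT combination against anti-PD1 and anti-CD40, and 8 for the interaction with anti-PD1. The compared groups alone gave 7 for HET anti-PD1 against IgG and 8 for the WT combination against anti-CD40. For HET combination against anti-CD40, no filter gave 10 and 1 added gave 12. Within L7 HET anti-PD1 gave 9, and within L6 the WT combination against anti-CD40 gave 8.

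Leaving out 1 library at a time gave 12 to 20, 4 to 10 and 8 to 17 lists for WT anti-PD1, anti-CD40 and combination against IgG, and 2 to 8, 19 to 23 and 18 to 24 for the same in HET. It gave 3 to 12, 8 to 21, 14 to 21 and 15 to 20 for HET against WT under IgG, anti-PD1, anti-CD40 and the combination. The combination against anti-PD1 and anti-CD40 gave 8 to 20 and 4 to 12 in WT and 19 to 21 and 3 to 14 in HET, and the interactions 8 to 20 (anti-PD1), 9 to 22 (anti-CD40) and 13 to 21 (combination).

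Single list medians crossed 0 with the L number in 12 of the 72 described. These were proliferation -0.17 (WT combination against IgG), muscle -0.15 (HET combination against IgG) and -1.36 (HET against WT, combination), inflammatory 0.68 (HET against WT, IgG), T cell 0.36 (HET against WT, anti-PD1), IFN-γ 0.97 and endothelial 0.13 (WT combination against anti-PD1), plasma cell -0.11 (HET combination against anti-PD1), IFN-γ -0.20 and MHC class II -0.29 (interaction with anti-CD40), and -0.71 and -0.95 (interaction with the combination). The neutrophil median (HET against WT, IgG) stayed below 0 with the L number, at -0.04, but its list test turned in direction against the other genes. Hypoxia turned to -0.03 within L7 (HET anti-PD1) and IFN-γ to 0.08 without WT anti-PD1 replicate 1 (WT combination against anti-PD1, -1.0 to 0.08 over the libraries left out). Other settings ended some calls without a turn. Library weights did so for T cell 0.68 and inflammatory 0.73 (WT anti-CD40 against IgG), melanocyte -0.01 and -0.22 (HET anti-PD1 and anti-CD40 against IgG), macrophage 0.47 and inflammatory -0.42 (HET against WT, IgG) and IFN-γ -0.14 (WT combination against anti-PD1). Quantile normalization did so for melanocyte -0.09 and -0.28 in the same 2 comparisons, the compared groups alone for melanocyte -0.26 (HET anti-PD1 against IgG), and the stricter filter for inflammatory 0.30 (WT anti-CD40 against IgG) and -0.17 (HET against WT, IgG). Adding 1 made 26 of 72 medians smaller by over 1.5 times, 11 of them by over 2 times, with all calls kept. These 11 were T cell 0.36 and B cell 0.30 (WT anti-PD1 against IgG), T cell 0.36 and inflammatory 0.31 (WT anti-CD40 against IgG), cytotoxic 0.95, 0.60 and 0.81 (HET anti-CD40 and combination against IgG, HET against WT under anti-CD40), T cell -0.28 (HET against WT, anti-PD1), neutrophil -0.79 (WT combination against anti-CD40) and 0.91 (interaction with the combination), and plasma cell 1.01 (HET combination against anti-PD1).

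Among calls that were kept, library weights also moved IFN-γ to 0.45 and endothelial to 0.31 (WT anti-PD1 against IgG), T cell to -0.62 (HET against WT, anti-PD1) and muscle to 2.39 (HET against WT, anti-CD40). With no filter B cell was at 0.55 (WT anti-PD1 against IgG) and conventional dendritic cell at 1.01 (HET against WT, anti-CD40), and with voom T cell at 1.13 (WT anti-PD1 against IgG). The stricter filter gave IFN-γ 1.47 (HET against WT, anti-CD40) and 1.04 (interaction with the combination), and the replicate block neutrophil -0.41 (WT combination against IgG). Of all 248 list calls, 84 turned in direction against the other genes under at least 1 alternative and 12 when 1 library was left out. Of 3057 values of 156 gene folds, 137 changed sign, 59 of them without 1 library and 32 with the L number. In all 61 folds changed sign at least once. The largest of these had an absolute log2 of 3.48, the value of Cd74 in the interaction with anti-CD40.

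The replicate number did not pair the samples: over 94 pairs of libraries with the same number the median correlation of their deviations was -0.023, and 4 of 30 libraries correlated best with their own number. With the replicate block limma called 0 genes in every comparison, the 17 list counts stayed within 1.5 times, and 2 of 72 list medians lost their call, proliferation at 0.04 (WT combination against IgG) and inflammatory at -0.36 (HET against WT, IgG). Depth limits Ifng, which had 0 reads in 2 groups, and 3 reads over a group served as the floor.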

Other observations

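HET IgG replicate 2 held more of some abundant transcripts and less of the long noncoding RNAs Xist and Neat1, and these genes were chosen after their values were seen. Its log2 value of mt-Co1, a mitochondrially encoded subunit of cytochrome oxidase, was 15.26 against 10.95 to 14.35 in the other 29 libraries, and that of mt-Nd1 13.52 against 10.02 to 11.80. Gapdh, a glycolytic enzyme gene, stood at 13.66 against 12.05 to 13.09. Neat1, which scaffolds nuclear paraspeckles, stood at 5.34 against 6.25 to 10.22, while Malat1 at 7.64 and Kcnq1ot1 at 2.01 lay within the 6.68 to 8.64 and 1.80 to 4.29 of the others. Without this library limma called 0 genes in each of the comparisons that use it, and the lists called were 2, 19 and 18 for HET anti-PD1, anti-CD40 and combination against IgG.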
